A study of Mus musculus with 24 samples.

How the data were processed

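Poly-A RNA from the left ventricle and septum of male C57BL/6 mouse hearts was sequenced as paired-end libraries on an Illumina NovaSeq instrument, per the labels' protocols. The 24 libraries fall into 4 groups of 6 by surgery and exposure: sham surgery and filtered air (Sham/Air), sham surgery and benzene (Sham/Benzene), transverse aortic constriction and filtered air (TAC/Air), and transverse aortic constriction and benzene (TAC/Benzene). Groups and replicate numbers were taken from the sample titles. The series design text states 4 groups of 6 hearts, which matches the 6 libraries per group. The sample labels do not name the mouse of each library, so p-values measure only the spread between these samples.

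The authors deposited 1 table of whole-number read counts per gene symbol, with 1 column per library and no normalization. The submitters' processing notes name FastQC 0.11.9, STAR, DESeq2 and the mm9 build. The counting program, the gene annotation and the strand setting are not given in the sources used here. Reads of near-identical genes and of overlapping genes can be lost or split in such a table, and counts of Hspa1a, Hspa1b, H2-Q6 and the globin genes are uncertain for that reason. No coordinates are given because the reference used here for gene properties is of another build.

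The table held 25229 gene symbols, none of them blank, and 5678 had no count in any library. Total counts ran from 4170660 to 14632231 per library. Genes were kept with edgeR 4.0.16 (R 4.3.3) by its filter on expression, with a minimum count of 10 and a minimum total of 15, which left 13571 genes. The genes left out held 0.0747% of all counts. Library sizes were scaled by TMM. The quasi-likelihood test with robust dispersion was fitted to all 24 libraries with 1 coefficient per group, and 6 contrasts were tested: TAC against sham in air, TAC against sham in benzene, benzene against air in sham, benzene against air in TAC, benzene against air averaged over surgery, and the surgery by benzene interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of genes in the text come from this test. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels in CPM, counts scaled to a common library size, used the TMM-scaled library sizes, and log2 CPM values used a prior count of 2.

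The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. There were 29 gene lists, and the list of genes encoded by the mitochondrial genome had no member among the tested genes and was not tested. The other 28 were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. Adjusted p-values of lists are those with the preset correlation unless an estimated one is named. Members are counted over those tested, which were 9 of 24 listed neutrophil genes and 6 of 27 listed lymphocyte genes. The filter asks for expression in only as many libraries as a group holds, so a gene high in a single group can enter through it. Cxcr2, at 0.614 CPM in TAC/Air and 2.36 CPM in TAC/Benzene, is of this kind. Shares such as 8 of 9 neutrophil genes higher, and list medians, can be raised in that way. Without the filter the neutrophil calls were kept. Named genes are the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 1 CPM over the libraries compared, leaving out unnamed gene models, together with Nppa, Nppb, Myh7, Myh6, Acta1 and Atp2a2 in each comparison and up to 4 members of each list with the smallest p. Where under 5 genes passed in a direction, the 5 with the smallest p were named as not passing. After values had been seen, the list part was shortened from 4 to at most 2 members per list, and to lists called in that comparison. Some genes that the rule names are not reported here and enter no count of named genes. Genes that the text names outside this rule are said to be so where they appear.

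The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, relative log expression size factors, no filter on low counts, a filter of a mean of at least 1 CPM, a fit of only the 2 groups compared, the replicate number as a block, and each library left out in turn. Offsets for the trend of each library with GC content and transcript length, with all libraries and without Sham/Air replicate 1, were chosen after seeing the data. The trends were loess curves with a span of 0.5 over genes with a mean count of at least 50. GC content and length came from the longest GENCODE vM21 transcript of each symbol, and 97.9% of the symbols were matched. The lists not called in any of the 6 comparisons with all libraries and the filter on low counts, of adipocyte, circadian, erythroid and blood, ribosomal protein and smooth muscle and pericyte genes, are given with the other observations, with the alternatives that called them. The procedure was tested on simulated counts for 13571 genes made for the comparison of benzene with air in TAC. Of 67 genes changed 1.5-fold 39 were recovered, of 67 changed 2-fold 60, and of 66 changed 4-fold 66, with 4 false calls among 13371 unchanged genes. The simulation drew independent noise from the dispersion trend, with no GC trend and no library apart, and changed only genes with a mean of at least 1 CPM. Its recovery and its false calls therefore do not give the rates in the real libraries. Gene properties and figures were computed in Python 3.11.15. Random regroupings of the libraries, 100 per comparison in each of 2 draws, were fitted in the same way.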

Results

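The series asked how inhaled benzene and pressure overload act together on the heart. Transverse aortic constriction (TAC) narrows the aorta and loads the left ventricle, and sham surgery is its control. After 1 week of recovery, mice breathed filtered air or 50 ppm benzene for 6 hours a day, 5 days a week, for 6 weeks. Gene counts were obtained for 6 libraries in each of the 4 groups. Total counts ranged from 4170660 to 12718494 in Sham/Air, from 9396445 to 14632231 in Sham/Benzene, from 10479981 to 13581729 in TAC/Air and from 10016860 to 13724100 in TAC/Benzene. Sham/Air replicate 1 had the lowest total and Spearman correlations of 0.932 to 0.947 with the other libraries, while the other 23 libraries correlated with each other at 0.971 to 0.982. Libraries within a group also differed along GC content, with rank correlations from -0.71 to 0.41 in Sham/Air, -0.50 to 0.44 in Sham/Benzene, -0.55 to 0.36 in TAC/Air and -0.31 to 0.40 in TAC/Benzene. Below, levels are mean CPM ± SD and log2 fold changes are given ± SE, with n = 6 libraries per group.

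**Figure D1:**
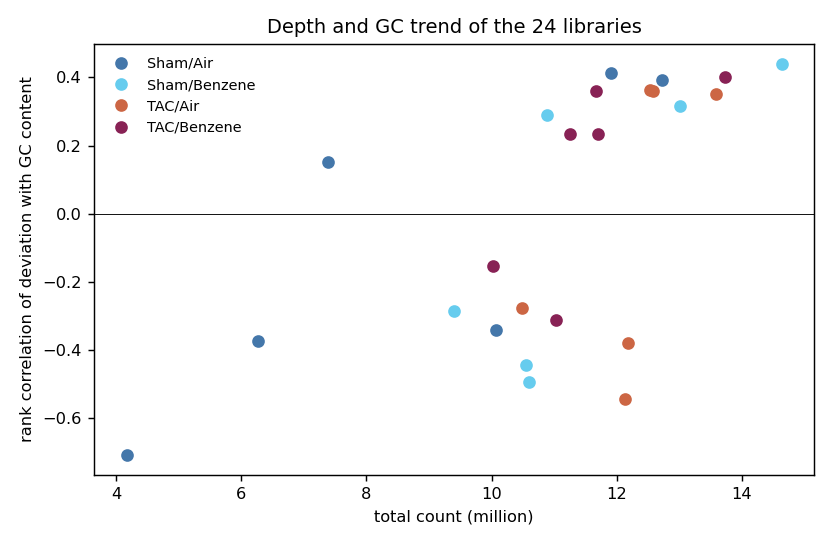
Each point is 1 of the 24 libraries, coloured by group, with its total count on the x axis and, on the y axis, the rank correlation across genes between its log2 deviation from the mean library and GC content. Sham/Air replicate 1 lies at the lower left, at 4170660 counts and -0.71, and every group has libraries on both sides of 0.

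The first comparison asked what TAC did to the heart in filtered air. The fetal gene program of the stressed ventricle rose, with 18 of 20 higher and 2 not passing, 18 higher and 1 lower adjusted over the list alone (adjusted p = 2.17e-53). Nppa, which encodes atrial natriuretic peptide, went from 256 ± 50.7 to 3609 ± 459 CPM, and the slow myosin heavy chain gene Myh7 from 350 ± 38.6 to 3222 ± 247 CPM. Brain natriuretic peptide gene Nppb rose by 2.04 ± 0.16 on the log2 scale, skeletal actin gene Acta1 by 2.46 ± 0.14 and the connective tissue growth factor gene Ccn2 by 2.62 ± 0.09. Adult contractile and calcium-handling genes fell, with 12 of 22 lower and 10 not passing, 12 lower adjusted over the list alone (adjusted p = 4.07e-06). The log2 fold change was -0.88 ± 0.13 for Myh6, the fast myosin heavy chain gene of the adult mouse ventricle, -0.65 ± 0.08 for the sarcoplasmic calcium pump gene Atp2a2 and -0.84 ± 0.11 for the potassium channel gene Kcnd2. All 6 TAC/Air libraries had more Nppa, Nppb, Myh7 and Acta1 than any Sham/Air library. Within Sham/Air, replicate 1 had the lowest Nppa at 155 CPM, Nppb at 123 CPM and Acta1 at 279 CPM, and the highest Myh6 and Atp2a2. Unlike Nppa, Nppb and Acta1, the fetal program gene Myh7 was highest there, at 424 CPM (next 353).

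**Figure D2:**
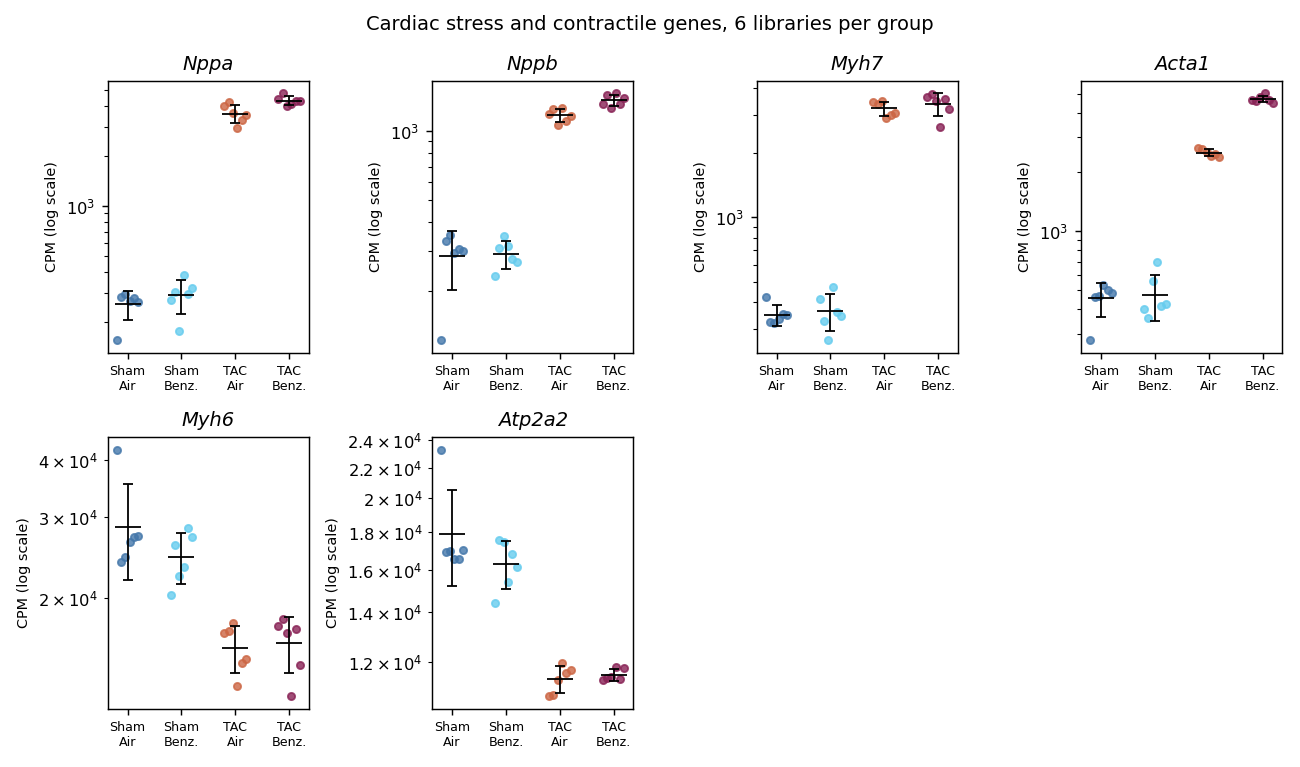
Each panel gives CPM on a log axis for 1 gene, with a point per library, a horizontal mark at the mean of the 6 libraries of a group and bars of 1 SD. Nppa, Nppb, Myh7 and Acta1 are higher in both TAC groups, Myh6 and Atp2a2 are lower, and Acta1 averages 4715 CPM in TAC/Benzene against 2512 CPM in TAC/Air.

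Extracellular matrix genes rose, with 43 of 46 higher and 3 not passing, 44 higher adjusted over the list alone (adjusted p = 7.25e-168). Thbs4, a thrombospondin of the matrix, rose by 4.07 ± 0.14 and the matrix protein gene Cilp by 3.89 ± 0.13. Fibroblast markers had 7 of 15 higher and 8 not passing, 8 higher adjusted over the list alone (adjusted p = 3.63e-10), among them Cthrc1 and the gelatinase gene Mmp2 at 1.54 ± 0.11. Among called genes with a symbol and a mean of at least 1 CPM, the highest log2 fold changes included Sprr1a at 5.68, Cthrc1 at 4.64, Comp at 4.35, Frem1 at 4.23, Ltbp2 at 4.14, Thbs4, Atp6v0a4 at 4.02, Col8a2 at 4.01 and Dio2, which encodes an enzyme that activates thyroid hormone, at 3.93. Cthrc1 was at 5.29 without Sham/Air replicate 5. Complement and coagulation genes had 10 of 18 higher, 1 lower and 7 not passing, 10 higher and 2 lower adjusted over the list alone (adjusted p = 0.00218). Serpinf1 was at 1.84 ± 0.10 and the complement inhibitor gene Serping1 at 0.64 ± 0.09. Macrophage and monocyte genes had 10 of 26 higher, 4 lower and 12 not passing, 13 higher and 5 lower adjusted over the list alone (adjusted p = 0.0113). The chemokine receptor gene Cx3cr1 was at 1.56 ± 0.14 and the Fc receptor gene Fcgr1 at 1.12 ± 0.17. Interferon and antigen-presentation genes had 8 of 30 higher and 22 not passing, 8 higher adjusted over the list alone (adjusted p = 0.0131), including Ifi44 at 0.72 ± 0.18 and Oasl2 at 0.42 ± 0.12.

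Fatty acid oxidation genes fell, with 23 of 31 lower and 8 not passing, 25 lower adjusted over the list alone (adjusted p = 5.55e-15). The log2 fold change was -0.82 ± 0.07 for the thiolase gene Acaa2 and -1.52 ± 0.14 for the thioesterase gene Acot1. Among called genes with a symbol and a mean of at least 1 CPM, the lowest log2 fold changes included Scgb1a1 at -5.49, Cyp1a1 at -2.78, Cenpf at -2.29, Ccl11 at -2.06, Fgf10 at -2.04, Kcnip1 at -1.89, Aqp4 at -1.88, Tll2 at -1.88 and Ankrd63 at -1.85. Scgb1a1 is a secretory protein gene of the airway epithelium, and its level was 6.32 ± 1.53 CPM in Sham/Air. Sham/Air replicate 1 had 145 CPM of the mitosis gene Cenpf and 19.3 CPM of the chemokine gene Ccl11, and the next highest Sham/Air library had 37.9 and 8.71 CPM. Without that library Cenpf was at -1.63, and without TAC/Air replicate 4 Cyp1a1 was at -3.39.

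A further 6 lists were called in air with the preset correlation and not with an estimated one. Respiratory chain genes had 22 of 47 lower and 25 not passing, 27 lower adjusted over the list alone (adjusted p = 1.99e-08, and adjusted p = 0.17 with an estimated correlation). Sdha was at -0.57 ± 0.07 and Ndufa9 at -0.39 ± 0.07. Immediate early genes had 11 of 19 higher and 8 not passing, 12 higher adjusted over the list alone (adjusted p = 2.31e-07, and adjusted p = 0.144 with an estimated correlation). The transcription factor genes Egr2 was at 3.01 ± 0.30 and Egr3 at 1.51 ± 0.21. Xenobiotic metabolism genes had 3 of 24 higher, 11 lower and 10 not passing, 3 higher and 13 lower adjusted over the list alone (adjusted p = 0.00279, and adjusted p = 0.144 with an estimated correlation). The alcohol dehydrogenase gene Adh1 was at -1.13 ± 0.16 and the sulfotransferase gene Sult1a1 at -1.01 ± 0.16. Cell cycle genes had 7 of 29 higher, 1 lower and 21 not passing, 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.00838, and adjusted p = 0.167 with an estimated correlation). Thymidylate synthase gene Tyms was at 1.08 ± 0.18. Endothelial activation genes had 3 of 22 higher and 19 not passing, 3 higher adjusted over the list alone (adjusted p = 0.0113, and adjusted p = 0.0995 with an estimated correlation). The sialomucin gene Cd34 was at 0.54 ± 0.06. Atrial, mesothelial and nerve markers had 4 of 12 higher, 3 lower and 5 not passing, 4 higher and 3 lower adjusted over the list alone (adjusted p = 0.0322, and adjusted p = 0.183 with an estimated correlation). Dkk3 was at 1.81 ± 0.17. Their median log2 fold change of -0.34 had the opposite sign to the upward test, and the call ended without Sham/Air replicate 2 (adjusted p = 0.0541) and without the low-count filter (adjusted p = 0.203), where the median was 0.12 over more members.

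In all, 1195 genes were higher and 998 lower after TAC in air, of 13571 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 390 and 120 of them changed at least 2-fold. Of 28 lists 14 were called, 8 of them also with an estimated correlation. With that correlation the camera adjusted p was 1.29e-09 for matrix genes, 0.0193 for macrophage and monocyte genes and 0.0478 for interferon genes. A fit of only these 2 groups called 1278 genes and ended the calls of Ifi44 and Oasl2, limma-voom called 3739 and GC and length offsets, chosen after seeing the data, 3595.

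The next comparison asked what TAC did in mice that breathed benzene. The fetal program rose here too, with 17 of 20 higher and 3 not passing, 17 higher and 1 lower adjusted over the list alone (adjusted p = 1.61e-64). The log2 fold change was 3.89 ± 0.16 for Nppa, 3.21 ± 0.12 for Myh7, 2.22 ± 0.16 for Nppb, 3.31 ± 0.15 for Acta1 and 2.38 ± 0.09 for Ccn2. Matrix genes had 40 of 46 higher, 1 lower and 5 not passing, 43 higher and 1 lower adjusted over the list alone (adjusted p = 1.13e-134). Thbs4 was at 3.99 ± 0.14 and Cilp at 3.52 ± 0.12. Fibroblast markers had 6 of 15 higher and 9 not passing, 8 higher and 1 lower adjusted over the list alone (adjusted p = 3.04e-07). The transcription factor gene Meox1 was at 2.1 ± 0.14. Adult contractile genes had 10 of 22 lower and 12 not passing, 11 lower adjusted over the list alone (adjusted p = 4.76e-04). Myh6 was at -0.62 ± 0.13, Atp2a2 at -0.50 ± 0.08 and Kcnd2 at -0.86 ± 0.11. Fatty acid oxidation genes had 22 of 31 lower and 9 not passing, 24 lower adjusted over the list alone (adjusted p = 1.39e-16). Acaa2 was at -1.02 ± 0.07. Neutrophil genes, of which 9 of 24 listed were expressed enough to be tested, had 8 of 9 higher and 1 not passing, 8 higher adjusted over the list alone (adjusted p = 1.11e-08). The calprotectin gene S100a9 was at 1.89 ± 0.20 and Retnlg at 2.52 ± 0.30. In air 0 of the 9 were higher and 1 lower (adjusted p = 0.603), and the difference was tested as the interaction, with adjusted p = 4.97e-29. Endothelial activation genes had 7 of 22 higher and 15 not passing, 9 higher adjusted over the list alone (adjusted p = 1.87e-04). E-selectin gene Sele was at 1.44 ± 0.15.

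By the same rule on level, the other highest log2 fold changes of TAC in benzene included Sprr1a at 5.12, Cthrc1 at 4.18, Ltbp2 at 3.97, Serpinb1c at 3.9, Nrip3 at 3.72, Ereg at 3.68 and Gdf15, a stress-induced cytokine gene, at 3.66. The lowest included Cyp1a1 at -5.11, Cacng6 at -3.7, Ccl11 at -3.37, Retnla at -2.58, Rp1 at -2.53, Aqp4 at -2.52, Apoa2 at -2.47, Cenpf at -2.33 and Cnmd at -2.28. Sham/Benzene replicate 1 had 28.9 CPM of Cyp1a1 and 17.6 CPM of Apoa2, against at most 6.09 and 5.46 CPM in the other replicates of its group. Without it Cyp1a1 was at -4.03 and Apoa2 at -1.45, and without Sham/Benzene replicate 4 Sprr1a was at 6.1 and Ereg at 4.27. Respiratory chain genes had 21 of 47 lower and 26 not passing, 24 lower adjusted over the list alone (adjusted p = 1.77e-08, and adjusted p = 0.225 with an estimated correlation). Sdha was at -0.55 ± 0.07 and Ndufs1 at -0.46 ± 0.07. Immediate early genes had 8 of 19 higher and 11 not passing, 9 higher adjusted over the list alone (adjusted p = 3.63e-07, and adjusted p = 0.198 with an estimated correlation). Fos was at 1.45 ± 0.14 and Egr2 at 2.28 ± 0.24. Xenobiotic metabolism genes had 1 of 24 higher, 10 lower and 13 not passing, 2 higher and 12 lower adjusted over the list alone (adjusted p = 0.00216, and adjusted p = 0.193 with an estimated correlation). The benzene-oxidizing enzyme gene Cyp2e1 was at -1.88 ± 0.21. The comparison called 1176 genes higher and 1081 lower, and 10 of 28 lists, 7 of them also with an estimated correlation. The camera adjusted p was then 7.15e-04 for neutrophil genes and 0.0181 for endothelial activation genes. Limma-voom called 4497 genes and GC and length offsets 3644.

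The responses to TAC in air and in benzene shared 1473 called genes. Of these 825 were higher in both and 644 lower in both, where independent lists would share 104 and 79.5, and 4 had opposite signs. Across all 13571 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.804. No library was used in both comparisons.

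**Figure D3:**
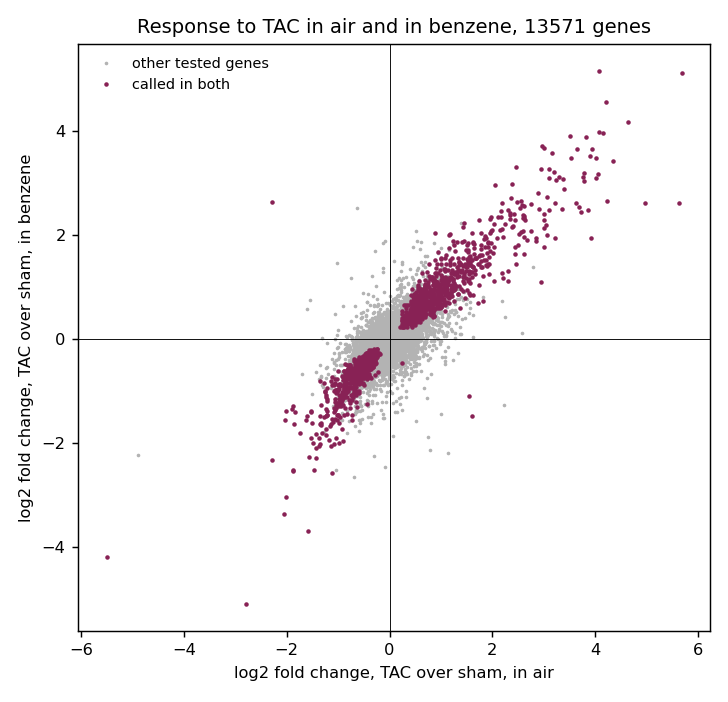
Each point is 1 of the 13571 tested genes, with its log2 fold change after TAC in air on the x axis and in benzene on the y axis, and coloured points are the 1473 genes called in both. Most coloured points lie in the quadrants where both changes have the same sign, and 4 do not.

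Benzene without pressure overload was examined in sham mice, where 3 of 13571 genes were called. Hspa1b, an inducible heat shock protein gene with the near-identical copy Hspa1a, was higher, and the lung epithelial genes Scgb1a1 and Sftpc were lower. Hspa1b was at 4.99 ± 0.78 CPM in Sham/Air and 54.9 ± 81.2 CPM in Sham/Benzene, where replicate 4 had 219 CPM and the next highest 30.4 CPM. Its log2 fold change was 3.45 ± 0.60, and 2.13 without Sham/Benzene replicate 4. Scgb1a1 had a log2 fold change of -3.14 ± 0.33 and Sftpc -2.57 ± 0.47. The genes with the next smallest p did not pass. Among higher genes these were Hspa1a at 2.98 ± 0.59, or 1.59 ± 0.33 without Sham/Benzene replicate 4, the chaperone gene Dnajb1 at 1.21 ± 0.26, Stat2 at 0.54 ± 0.12 and Ttr at 4.2 ± 0.91, and among lower genes Kit at -0.63 ± 0.14, Spon1 at -0.33 ± 0.07 and Cxcr4 at -0.59 ± 0.14. Nppa at 0.18 ± 0.15, Nppb at 0.04 ± 0.15, Myh7 at 0.06 ± 0.11, Myh6 at -0.22 ± 0.13, Acta1 at 0.06 ± 0.14 and Atp2a2 at -0.13 ± 0.08 did not pass either. Without Sham/Air replicate 1 they were, in the same order, at 0.08, -0.12, 0.12, -0.07, -0.04 and -0.04. Of 12 other lung markers, 6 had their highest mean in Sham/Air. Leaving out any 1 of the 6 Sham/Air libraries ended the calls of Hspa1b (adjusted p = 0.0849 to 0.137) and Sftpc, as did Sham/Benzene replicates 2 to 6 for Sftpc (adjusted p = 0.0506 to 0.26 over all of these). The count was 1 without Sham/Air replicates 2, 3, 4, 5 or 6 in turn, and it was 5 without Sham/Benzene replicate 1.

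In sham mice 5 of the 28 lists were called with the preset correlation and 0 with an estimated one. Other lists were called under alternatives. Without Sham/Air replicate 1 macrophage and monocyte genes were called lower (median -0.11, adjusted p = 0.00391) and complement genes higher (median 0.09, adjusted p = 0.0164). GC and length offsets called the macrophage and p53 response lists (adjusted p = 0.033 and 0.0332). Those offsets on 23 libraries called the macrophage, interferon and complement lists (adjusted p = 0.00443, 0.0496 and 0.0099). Chaperone and heat shock genes, at a median log2 fold change of 0.14, had 1 of 29 higher and 28 not passing, 5 higher adjusted over the list alone (adjusted p = 6.49e-04, and adjusted p = 0.181 with an estimated correlation). Cell cycle genes, at a median of -0.25, had none of 29 passing, also when adjusted over the list alone (adjusted p = 6.49e-04, and adjusted p = 0.17 with an estimated correlation). Mki67 was at -0.72 ± 0.26 and Mcm6 at -0.31 ± 0.12. The highest Sham/Air library, replicate 1, stood apart in Mki67 (20.2 CPM, next 9.27) and in Cenpf of the same list (145 CPM, next 37.9). Without it Mki67 was at -0.41 and Mcm6 at -0.23, and the list stayed called at a median of -0.19 (adjusted p = 0.0164). That median was -0.16 without Sham/Air replicate 3 and -0.13 without Sham/Benzene replicate 2. Immediate early genes, at a median of 0.29, had none of 19 passing, also when adjusted over the list alone (adjusted p = 6.49e-04, and adjusted p = 0.369 with an estimated correlation). Egr2 was at 1.11 ± 0.34 and Fosl2 at 0.30 ± 0.12. Matrix genes, at a median of 0.12, had none of 46 passing, 2 higher adjusted over the list alone (adjusted p = 9.53e-04, and adjusted p = 0.332 with an estimated correlation). Thbs1 was at 0.59 ± 0.16 and Fmod at 0.81 ± 0.23 without passing over all genes. Atrial, mesothelial and nerve markers, at a median of 0.56, had none of 12 passing, 2 higher adjusted over the list alone (adjusted p = 6.49e-04, and adjusted p = 0.17 with an estimated correlation). Dkk3 was at 0.63 ± 0.17 and S100b at 0.59 ± 0.20 without passing over all genes. Sham/Benzene replicate 4 had the highest level of its group in Dnajb1 (98.1 CPM, next 45.5), Egr2 (4.25, next 1.44), Thbs1 (57.1, next 29.0), Fmod (21.7, next 11.5) and Dkk3 (53.3, next 26.8). Without it Egr2 was at 0.57, Thbs1 at 0.33, Fmod at 0.50 and Dkk3 at 0.35. The immediate early and the matrix list were then not called (adjusted p = 0.126 for each), at medians of 0.12 and 0.02, and the atrial, mesothelial and nerve list was called at a median of 0.31 (adjusted p = 0.0205). Without Sham/Air replicate 1 the immediate early median was 0.15 (adjusted p = 0.0192). At an unadjusted p under 0.05 edgeR gave 777 genes, where chance alone gives about 679. DESeq2 called 28 genes, limma-voom 6, GC and length offsets 18, and a fit without the low-count filter or of only these 2 groups 1. The adjusted p of Hspa1b was 0.187 with limma-voom, 0.0506 without the filter and 0.994 in the fit of only 2 groups, and that of Sftpc 0.057, 0.157 and 0.818.

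Benzene in mice with TAC raised neutrophil genes, with 8 of 9 higher and 1 not passing, 8 higher adjusted over the list alone (adjusted p = 4.01e-56, and adjusted p = 3.41e-09 with an estimated correlation) and a median log2 fold change of 1.90. S100a9 went from 4.26 ± 0.937 CPM in TAC/Air to 18.6 ± 1.48 CPM in TAC/Benzene, its partner S100a8 from 3.12 ± 0.948 to 11.7 ± 2.19 CPM, and the resistin-like gene Retnlg from 0.601 ± 0.372 to 4.52 ± 0.99 CPM. The chemokine receptor gene Cxcr2 rose by 1.91 ± 0.34 on the log2 scale, the lectin gene Clec4d by 1.56 ± 0.35 and Csf3r, the receptor gene for granulocyte colony-stimulating factor, by 1.17 ± 0.17. Lipocalin gene Lcn2 rose by 1.76 ± 0.17, the neutrophil attractant gene Cxcl1 by 1.5 ± 0.30, angiotensinogen gene Agt by 1.14 ± 0.21 and P-selectin gene Selp by 1.07 ± 0.22. All 6 TAC/Benzene libraries had more S100a8, S100a9, Retnlg and Lcn2 than any library of the other groups. The erythroid and blood list had a mean log2 fold change of -0.04 and a downward test, at a median of 0.07 (adjusted p = 0.561).

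Interferon and antigen-presentation genes had 4 of 30 lower and 26 not passing, 8 lower adjusted over the list alone (adjusted p = 6.12e-21). The class II genes H2-Aa and H2-Ab1, which present peptides to helper T cells, had log2 fold changes of -0.74 ± 0.08 and -0.71 ± 0.09. Macrophage and monocyte genes had 2 of 26 lower and 24 not passing, 11 lower adjusted over the list alone (adjusted p = 1.04e-18). Cx3cr1 was at -0.88 ± 0.13 and the macrophage marker gene Adgre1 at -0.46 ± 0.09. Cell cycle genes had 1 of 29 lower and 28 not passing, 3 lower adjusted over the list alone (adjusted p = 1.78e-09). The ribonucleotide reductase gene Rrm2 was at -0.84 ± 0.19, and Mcm3 at -0.42 ± 0.11 did not pass. Complement and coagulation genes had 1 of 18 higher and 17 not passing, 1 higher and 3 lower adjusted over the list alone (adjusted p = 1.47e-06). Their median was -0.22, in the direction of the downward test, while the clusterin gene Clu was at 0.33 ± 0.07 and C7 at -0.41 ± 0.12, the latter not passing. Glucocorticoid-responsive genes had 4 of 17 higher and 13 not passing, 7 higher adjusted over the list alone (adjusted p = 1.06e-12), including Lcn2 and the metallothionein gene Mt2 at 1.0 ± 0.20. The fetal program had 3 of 20 higher and 17 not passing, 5 higher adjusted over the list alone (adjusted p = 2.58e-10), including Acta1 at 0.91 ± 0.14 and the NAD synthesis gene Nmrk2 at 0.76 ± 0.13. Nppa at 0.26 ± 0.15, Nppb at 0.22 ± 0.15, Myh7 at 0.07 ± 0.11, Myh6 at 0.04 ± 0.13 and Atp2a2 at 0.02 ± 0.08 did not pass.

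**Figure D4:**
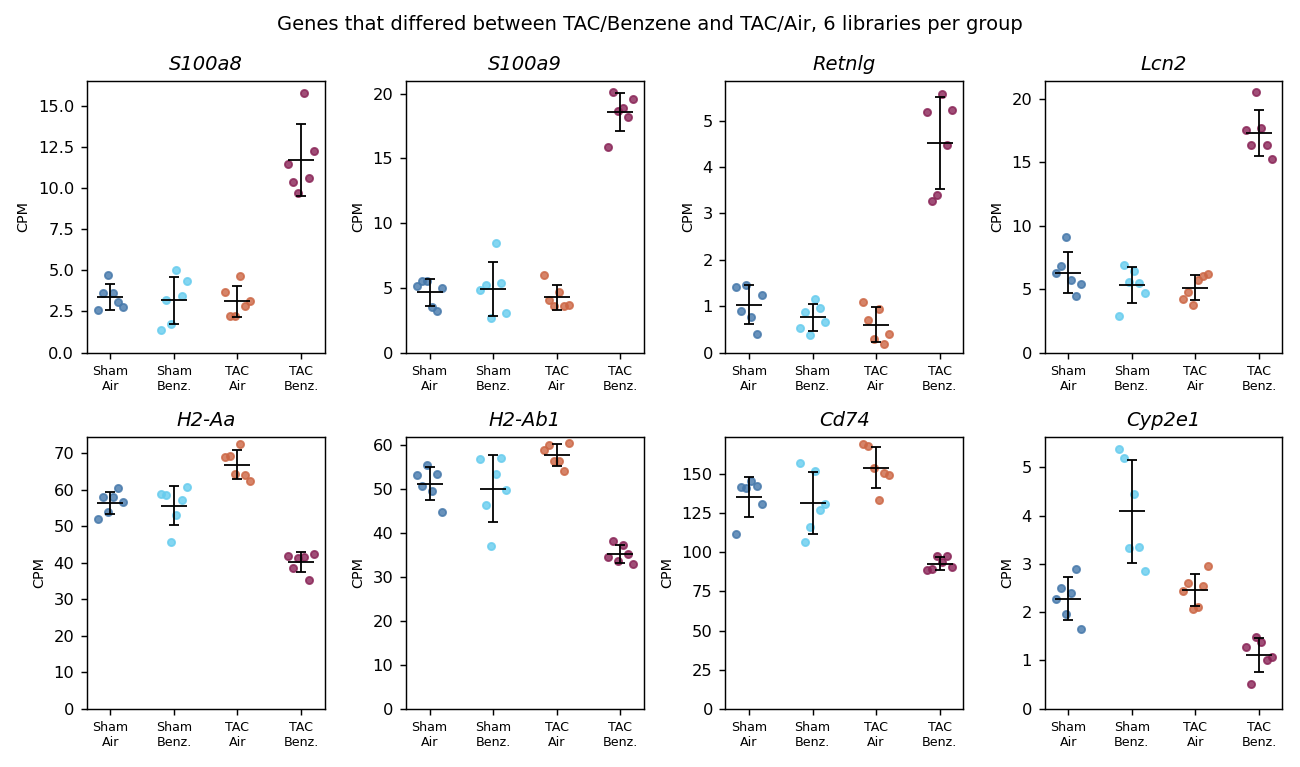
Each panel gives CPM for 1 gene on an axis that starts at 0, with a point per library, a horizontal mark at the mean of the 6 libraries of a group and bars of 1 SD. The means of S100a8, S100a9, Retnlg and Lcn2 are highest in TAC/Benzene, and those of H2-Aa, H2-Ab1, Cd74 and Cyp2e1 are lowest there.

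Among called genes with a symbol and a mean of at least 1 CPM, the 10 lowest log2 fold changes of benzene in TAC were Clec3a at -2.15 ± 0.31, Chad at -1.6 ± 0.24, Car3 at -1.57 ± 0.29, Cyp2e1 at -1.14 ± 0.22, Snrpn at -1.02 ± 0.23, Efemp1 at -0.99 ± 0.20, Gatm at -0.93 ± 0.15, Ecrg4 at -0.93 ± 0.20, the tenascin gene Tnc at -0.93 ± 0.21 and Wif1 at -0.92 ± 0.19. Clec3a and Chad are known from cartilage, and Car3 is a carbonic anhydrase gene of fat and muscle. Cytokine genes had 2 of 25 higher and 23 not passing, 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.00118), Lcn2 and Cxcl1 being the members higher over all genes. Chaperone and heat shock genes, at a median of 0.14, had none of 29 passing, 1 higher adjusted over the list alone (adjusted p = 1.64e-05). Manf was at 0.38 ± 0.10 and Hspb1 at 0.57 ± 0.23. Lymphocyte genes, at a median of -0.47, had none of 6 passing, 1 lower adjusted over the list alone (adjusted p = 0.0191). The B cell genes Cd79b was at -0.82 ± 0.25 and Pax5 at -0.68 ± 0.45. Fibroblast markers, at a median of -0.12, had none of 15 passing, 1 lower adjusted over the list alone (adjusted p = 0.0225). Dpt was at -0.23 ± 0.06 and Pdgfra at -0.23 ± 0.11. Endothelial markers, at a median of 0.07, had none of 18 passing, also when adjusted over the list alone (adjusted p = 0.0191). Cdh5 was at 0.20 ± 0.07 and Car4 at 0.42 ± 0.14. The lymphocyte and fibroblast lists were not called without TAC/Air replicate 3 (adjusted p = 0.0509 and 0.0545), nor the endothelial list without TAC/Air replicate 4 (adjusted p = 0.0554).

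Another 6 lists were called for benzene in TAC with the preset correlation and not with an estimated one. Matrix genes had 2 of 46 lower and 44 not passing, 3 lower adjusted over the list alone (adjusted p = 0.00484, and adjusted p = 0.268 with an estimated correlation), including Tnc and Thbs2 at -0.55 ± 0.11. Glycolysis and hypoxia genes had 2 of 30 higher and 28 not passing, 3 higher adjusted over the list alone (adjusted p = 0.00144, and adjusted p = 0.244 with an estimated correlation). Pfkp was at 0.40 ± 0.07 and Bnip3 at 0.32 ± 0.07. Endothelial activation genes had 2 of 22 higher and 20 not passing, 3 higher adjusted over the list alone (adjusted p = 0.0123, and adjusted p = 0.0925 with an estimated correlation), including Selp and Sele at 0.83 ± 0.15. Antioxidant genes had 2 of 24 higher and 22 not passing, 3 higher adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.268 with an estimated correlation), including the metallothionein genes Mt2 and Mt1 at 0.67 ± 0.16. Immediate early genes, at a median of 0.20, had none of 19 passing, 1 higher adjusted over the list alone (adjusted p = 2.26e-04, and adjusted p = 0.268 with an estimated correlation). Fos was at 0.54 ± 0.14 and Zfp36 at 0.42 ± 0.22. Atrial, mesothelial and nerve markers, at a median of -0.23, had none of 12 passing, also when adjusted over the list alone (adjusted p = 0.0379, and adjusted p = 0.232 with an estimated correlation). Dkk3 was at -0.45 ± 0.16 and S100b at -0.38 ± 0.18. The antioxidant call ended without TAC/Air replicates 3 to 6 or TAC/Benzene replicate 4 in turn (adjusted p = 0.0545 to 0.118), and the atrial, mesothelial and nerve call without TAC/Air replicates 1, 2 or 3 or TAC/Benzene replicates 3, 5 or 6 (adjusted p = 0.0542 to 0.139). The immediate early median was 0.30 without TAC/Air replicate 2, and the atrial, mesothelial and nerve median -0.15 without TAC/Benzene replicate 5. GC and length offsets ended the lymphocyte, antioxidant and atrial, mesothelial and nerve calls (adjusted p = 0.0649 for each), and a fit of only these 2 groups ended the lymphocyte call (adjusted p = 0.124). With the offsets the medians of these 3 lists were -0.468, 0.0084 and -0.239, against -0.472, 0.0155 and -0.230 without them.

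The comparison called 40 genes higher and 39 lower, 12 and 7 of them changed at least 2-fold, and 18 of 28 lists, 12 of them also with an estimated correlation. Under the latter the camera adjusted p was 0.0214 for cytokine, 0.047 for chaperone, 0.0407 for lymphocyte and for fibroblast, and 0.0358 for endothelial genes. At an unadjusted p under 0.05 edgeR gave 837 genes, where chance alone gives about 679. Limma-voom called 556 genes, DESeq2 171, a fit of only these 2 groups 276 and GC and length offsets 241, and the count was 52 without TAC/Benzene replicate 2. Of 34 named genes called, 24 kept the call whichever library was left out. The call ended without any 1 of 12 libraries for Mt1, 11 for Tnc, 10 for Rrm2, 8 for Snrpn, 7 for Clec4d, 6 for Bnip3, 6 for Ecrg4 and 4 for Wif1, of the 12 compared, and without TAC/Benzene replicate 2 for Efemp1 (adjusted p = 0.0538) and TAC/Air replicate 5 for Mt2 (adjusted p = 0.0552). GC and length offsets ended the call of Clu, at 0.28 with a wider standard error of 0.18 (adjusted p = 0.641), and a fit without the low-count filter those of Bnip3, Clu, Mt1 and Rrm2 (adjusted p = 0.0782, 0.0517, 0.0707 and 0.0555).

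Averaged over surgery, benzene raised the heat shock genes Hspa1b by 1.99 ± 0.40 and Hspa1a by 1.93 ± 0.40 on the log2 scale. In TAC mice alone Hspa1b was at 0.53 ± 0.55 and Hspa1a at 0.88 ± 0.55 without passing, against 3.45 ± 0.60 and 2.98 ± 0.59 in sham mice, or 2.13 and 1.59 without Sham/Benzene replicate 4, and the interaction did not pass (adjusted p = 0.269 and 0.78). Without Sham/Benzene replicate 4, which had 219 CPM of Hspa1b (next 30.4) and 184 CPM of Hspa1a (next 25.3), the averaged values were 1.33 and 1.235, and both stayed called (adjusted p = 0.00907 and 0.00989). Neutrophil genes had 4 of 9 higher and 5 not passing, 7 higher adjusted over the list alone (adjusted p = 1.21e-20). In sham mice alone none of the 9 passed, at a median of 0.04 (adjusted p = 0.854), against a median of 1.90 in TAC mice. Retnlg was at 1.31 ± 0.25, S100a9 at 1.13 ± 0.15, S100a8 at 0.91 ± 0.17 and Csf3r at 0.82 ± 0.13. Agt rose by 0.78 ± 0.15, Lcn2 by 0.77 ± 0.12, Mt2 by 0.75 ± 0.15 and the acute phase gene Serpina3n by 0.56 ± 0.10. From Sham/Air to Sham/Benzene, Lcn2 went from 6.29 to 5.32 CPM, Retnlg from 1.03 to 0.758 and S100a8 from 3.38 to 3.18. S100a9 went from 4.64 to 4.93 CPM and Agt from 3.38 to 4.70. The interaction was called for Lcn2, Retnlg, S100a8 and S100a9. Acta1 at 0.49 ± 0.10, Fhl1 at 0.40 ± 0.08, the cell cycle inhibitor gene Cdkn1a at 0.53 ± 0.11 and the endoplasmic reticulum stress gene Manf at 0.34 ± 0.07 were also higher. Acta1 had 455 CPM in Sham/Air and 475.7 in Sham/Benzene, against 2512 in TAC/Air and 4715 in TAC/Benzene. Its interaction did not pass. The 9 lower genes were Smoc1 at -0.65 ± 0.12, Col6a6 at -0.58 ± 0.12, Mylk4 at -0.57 ± 0.09, Gatm at -0.57 ± 0.11, Cx3cr1 at -0.52 ± 0.10, Spon1 at -0.31 ± 0.05 and the antigen-presentation genes Cd74 at -0.39 ± 0.07, H2-Aa at -0.38 ± 0.05 and H2-Ab1 at -0.37 ± 0.06. Cd74 had 135.5 CPM in Sham/Air and 131.7 CPM in Sham/Benzene, H2-Aa 56.4 and 55.7, and H2-Ab1 51.1 and 50.0. The interaction was called for each of these antigen-presentation genes. Nppa at 0.22 ± 0.10, Nppb at 0.13 ± 0.11, Myh7 at 0.06 ± 0.08, Myh6 at -0.09 ± 0.09 and Atp2a2 at -0.06 ± 0.06 did not pass.

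Among lists averaged over surgery, macrophage and monocyte genes, at a median of -0.18, had 1 of 26 lower and 25 not passing, 9 lower adjusted over the list alone (adjusted p = 1.28e-11). Mpeg1 was at -0.30 ± 0.07 without passing over all genes. Cell cycle genes, at a median of -0.29, had none of 29 passing, 7 lower adjusted over the list alone (adjusted p = 5.44e-10). Mcm6 was at -0.31 ± 0.08 and Rrm2 at -0.50 ± 0.14. Lymphocyte genes, at a median of -0.42, had none of 6 passing, 2 lower adjusted over the list alone (adjusted p = 0.00725). The B cell genes Ms4a1 was at -1.07 ± 0.32 and Pax5 at -0.91 ± 0.34. Interferon and antigen-presentation genes had 3 of 30 lower and 27 not passing, 4 lower adjusted over the list alone (adjusted p = 1.78e-07). Glucocorticoid-responsive genes had 3 of 17 higher and 14 not passing, 6 higher adjusted over the list alone (adjusted p = 3.88e-08). Chaperone and heat shock genes had 3 of 29 higher and 26 not passing, 7 higher adjusted over the list alone (adjusted p = 3.86e-08). The fetal program had 2 of 20 higher and 18 not passing, 6 higher adjusted over the list alone (adjusted p = 1.69e-06). In sham mice alone the macrophage, interferon, glucocorticoid and fetal lists were not called (camera adjusted p = 0.102, 0.478, 0.269 and 0.414). Their medians were -0.09, -0.0069, 0.16 and 0.06 there and -0.37, -0.27, 0.18 and 0.24 in TAC mice. The interaction was called for each of them. The lymphocyte list was not called in sham mice either (adjusted p = 0.122). With the preset correlation the cell cycle and chaperone lists were called in both. In Hspa1b, Hspa1a and Egr2, Sham/Benzene replicate 4 was the highest library of its group, at 219, 184 and 4.25 CPM.

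The calls of another 6 lists averaged over surgery were lost with an estimated correlation. Glycolysis genes had none of 30 passing, 3 higher adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.383 with an estimated correlation). Bnip3 was at 0.18 ± 0.05 and Egln3 at 0.19 ± 0.05. That call ended without Sham/Air replicate 1 (adjusted p = 0.121) or with GC and length offsets (adjusted p = 0.235). Cytokine genes had 1 of 25 higher and 24 not passing, 2 higher adjusted over the list alone (adjusted p = 0.0234, and adjusted p = 0.10 with an estimated correlation). Cxcl1 was at 0.79 ± 0.22 without passing over all genes. The cytokine call ended without Sham/Air replicate 6, TAC/Air replicate 2 or TAC/Benzene replicate 4 (adjusted p = 0.0512 to 0.0612). Complement genes had none of 18 passing, also when adjusted over the list alone (adjusted p = 0.0437, and adjusted p = 0.0689 with an estimated correlation). C3 was at -0.19 ± 0.06 and Clu at 0.14 ± 0.05. In sham mice alone the complement median was 0.07 with an upward test (camera adjusted p = 0.361). It was -0.22 in TAC mice, and the interaction was called. The complement call ended without any 1 of 11 libraries (adjusted p = 0.0515 to 0.0883) and with a filter of at least 1 CPM (adjusted p = 0.0686). Antioxidant genes had 1 of 24 higher and 23 not passing, 3 higher adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.204 with an estimated correlation). Mt1 was at 0.50 ± 0.11 without passing over all genes. Genes of the p53 response had 1 of 24 higher and 23 not passing, 1 higher adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.0696 with an estimated correlation). The death receptor gene Tnfrsf10b was at 0.46 ± 0.15 without passing over all genes. Immediate early genes had none of 19 passing, 1 higher adjusted over the list alone (adjusted p = 9.52e-07, and adjusted p = 0.161 with an estimated correlation). Egr2 was at 0.75 ± 0.20 and Fosl2 at 0.24 ± 0.08 without passing over all genes. Without Sham/Benzene replicate 4 Egr2 was at 0.48 and Fosl2 at 0.20.

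In all 17 genes were higher and 9 lower averaged over surgery, and 14 of 28 lists were called, 8 of them also with an estimated correlation. The camera adjusted p with it was 1.2e-05 for neutrophil genes and 0.0189 for lymphocyte and for chaperone genes. At an unadjusted p under 0.05 edgeR gave 983 genes, where chance alone gives about 679. The count was 101 without Sham/Air replicate 1, 17 without TAC/Air replicate 5 and 16 without TAC/Benzene replicate 4. Of the 24 libraries, leaving out any 1 of 17 ended the call of Hspa1a, 11 that of Hspa1b, 11 Manf, 11 Fhl1, 9 Cdkn1a, 7 Agt, 4 Acta1, 4 Col6a6 and 2 Mt2. DESeq2 called 103 genes, limma-voom 187 and GC and length offsets 145, and the offsets ended the calls of H2-Ab1 and Acta1 (adjusted p = 0.0795 and 0.0763). With them H2-Ab1 was at -0.52 ± 0.14, a larger change with a wider standard error, and Acta1 at 0.36 ± 0.10. Limma-voom ended the call of Hspa1b (adjusted p = 0.0641) and a fit without the low-count filter that of Hspa1a (adjusted p = 0.051).

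The interaction asked whether benzene acted differently after TAC than after sham surgery. Neutrophil genes differed, with 4 of 9 higher and 5 not passing, 7 higher adjusted over the list alone (adjusted p = 4.97e-29) and a median difference of 1.41. The log2 difference was 3.14 ± 0.50 for Retnlg, 1.98 ± 0.30 for S100a9, 1.98 ± 0.34 for S100a8 and 1.97 ± 0.25 for Lcn2. Sele differed by 1.2 ± 0.23, the sarcomere protein gene Myot by 0.69 ± 0.12, the glucocorticoid-induced gene Fkbp5 by 0.67 ± 0.12 and the phosphofructokinase gene Pfkp by 0.47 ± 0.10. Interferon and antigen-presentation genes had 3 of 30 lower and 27 not passing, 7 lower adjusted over the list alone (adjusted p = 7.17e-15). H2-Aa was at -0.71 ± 0.11 and H2-Ab1 at -0.68 ± 0.13. Among called genes with a symbol and a mean of at least 1 CPM, the 10 lowest differences were Clec3a at -3.09 ± 0.45, Chad at -2.64 ± 0.35, Car3 at -1.95 ± 0.39, Cyp2e1 at -1.95 ± 0.30, Ecrg4 at -1.85 ± 0.34, Wif1 at -1.3 ± 0.27, the interferon-induced gene Tgtp2 at -0.998 ± 0.19, Scara3 at -0.91 ± 0.18, the macrophage lectin gene Mgl2 at -0.81 ± 0.17 and H2-Q6, which has near-identical copies, at -0.80 ± 0.16. Nppa at 0.08 ± 0.21, Nppb at 0.18 ± 0.22, Myh7 at 0.01 ± 0.16, Myh6 at 0.25 ± 0.18, Acta1 at 0.85 ± 0.19, Nmrk2 at 0.90 ± 0.20 and Atp2a2 at 0.15 ± 0.11 did not pass.

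Macrophage and monocyte genes, at a median difference of -0.19, had none of 26 passing, 3 lower adjusted over the list alone (adjusted p = 8.59e-06). Adgre1 was at -0.50 ± 0.13 and Cx3cr1 at -0.71 ± 0.20 without passing over all genes. Complement and coagulation genes, at a median difference of -0.24, had none of 18 passing, 1 higher adjusted over the list alone (adjusted p = 6.74e-06). C7 was at -0.46 ± 0.17 and Clu at 0.38 ± 0.09 without passing over all genes. Glucocorticoid-responsive genes had 2 of 17 higher and 15 not passing, 2 higher adjusted over the list alone (adjusted p = 5.98e-05). The fetal program, at a median difference of 0.18, had none of 20 passing, 6 higher and 2 lower adjusted over the list alone (adjusted p = 2.19e-04). Atrial, mesothelial and nerve markers, at a median difference of -0.77, had none of 12 passing, 2 lower adjusted over the list alone (adjusted p = 7.83e-06). Dkk3 was at -1.09 ± 0.24 and S100b at -0.97 ± 0.27 without passing over all genes. Matrix genes, at a median difference of -0.17, had none of 46 passing, 6 lower adjusted over the list alone (adjusted p = 1.74e-06, and adjusted p = 0.0819 with an estimated correlation). Fmod was at -1.16 ± 0.30 and Thbs1 at -0.77 ± 0.22 without passing over all genes. Dkk3, Fmod and Thbs1 were highest in Sham/Benzene in replicate 4, at 53.3, 21.7 and 57.1 CPM, with the next libraries at 26.8, 11.5 and 29.0 CPM. Without that replicate the atrial, mesothelial and nerve median was -0.47 and the matrix median -0.11, and both lists stayed called. In all 9 genes had a higher and 14 a lower benzene effect after TAC, and 8 of 28 lists were called, 7 of them also with an estimated correlation. At an unadjusted p under 0.05 edgeR gave 637 genes, fewer than the 679 or so that chance alone gives. The count was 49 without Sham/Air replicate 1 and 15 without Sham/Air replicate 4. Of the 24 libraries, leaving out any 1 of 20 ended the call of Pfkp, 18 that of Wif1, 16 Mgl2, 14 Scara3, 12 H2-Q6 and 10 Car3, and leaving out Sham/Air replicate 4 that of Sele (adjusted p = 0.052). DESeq2 called 57 genes, limma-voom 93 and GC and length offsets 55, and the offsets ended the calls of Pfkp, H2-Q6 and H2-Ab1, then at 0.39 ± 0.10, -0.76 ± 0.22 and -0.54 ± 0.28 (adjusted p = 0.0862, 0.163 and 0.591). A fit without the low-count filter ended those of Pfkp, Scara3 and Mgl2 (adjusted p = 0.174, 0.0521 and 0.0594).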

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

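The tests of GC content on the neutrophil genes, of globin transcripts, of lung markers and of lung transcripts in TAC/Air were chosen after the results were seen. Among 540 groups of 6 libraries tested for a library apart from the rest, 74 had one. Chance gives about 1 in 20, or 27, if the values are normal and independent. Nearly all were CPM of genes that the text names, and many of the flags fall on Sham/Air replicate 1 and Sham/Benzene replicate 4. The flags are therefore not separate events, and 27 is only a rough guide. Sham/Air replicate 1 was highest of its group in Atp2a2 at 23300 CPM (next 17000), Atp6v0a4 at 2.27 CPM (next 0.501), C3 at 382 CPM (next 285), Ccl11 at 19.3 CPM (next 8.71), Cenpf at 145 CPM (next 37.9), Clec3a at 7.96 CPM (next 2.9) and Clu at 955 CPM (next 866). It was also highest in Ereg at 1.7 CPM (next 0.429), Fgf10 at 5.4 CPM (next 1.63), Ifi44 at 8.52 CPM (next 5.48), Kcnd2 at 43.5 CPM (next 33.7), Kit at 14.5 CPM (next 10.3), Mki67 at 20.2 CPM (next 9.27) and Myh6 at 42100 CPM (next 27300). It was also highest in Myh7 at 424 CPM (next 353), Mylk4 at 570 CPM (next 354), Pfkp at 69.6 CPM (next 62.1), Sdha at 2440 CPM (next 2100), Serpinb1c at 1.14 CPM (next 0.689), Sult1a1 at 92.6 CPM (next 46.9) and Tgtp2 at 23 CPM (next 15.1). It was also highest in Thbs2 at 75.3 CPM (next 55.6) and Thbs4 at 19.9 CPM (next 13.7). Sham/Air replicate 1 was lowest of its group in Acaa2 at 994 CPM (next 1120), Acta1 at 279 CPM (next 463), Cdkn1a at 8.81 CPM (next 16.6), Dnajb1 at 6.25 CPM (next 17.9), Fosl2 at 19 CPM (next 29.3), Hspb1 at 57.1 CPM (next 163) and Ltbp2 at 3.41 CPM (next 9.64). It was also lowest in Meox1 at 9.66 CPM (next 15.6), Mmp2 at 43.5 CPM (next 74.3), Mt1 at 73.6 CPM (next 167), Mt2 at 7.39 CPM (next 26), Nppa at 155 CPM (next 263), Nppb at 123 CPM (next 295) and Serpina3n at 15.6 CPM (next 25.3). It was also lowest in Stat2 at 13.6 CPM (next 19.7). Sham/Benzene replicate 4 was highest of its group in Cxcl1 at 5.34 CPM (next 2.43), Dkk3 at 53.3 CPM (next 26.8), Dnajb1 at 98.1 CPM (next 45.5), Egr2 at 4.25 CPM (next 1.44), Egr3 at 6.85 CPM (next 3.14), Fkbp5 at 27.9 CPM (next 24.4) and Fmod at 21.7 CPM (next 11.5). It was also highest in Hspa1a at 184 CPM (next 25.3), Hspa1b at 219 CPM (next 30.4), Ltbp2 at 19 CPM (next 11.6), Mgl2 at 23.3 CPM (next 17.3), Thbs1 at 57.1 CPM (next 29) and Thbs4 at 22.4 CPM (next 15.1). Sham/Benzene replicate 1 was highest of its group in Apoa2 at 17.6 CPM (next 5.46), Cyp1a1 at 28.9 CPM (next 6.09), Gatm at 7.49 CPM (next 5.34), Nmrk2 at 22 CPM (next 13.4) and Ttr at 11.1 CPM (next 3.24). Other libraries apart from their group were found for Sele in Sham/Air replicate 5 (lowest, 2.02 CPM, next 2.6), Snrpn in Sham/Air replicate 5 (lowest, 2.34 CPM, next 4.37), Acot1 in Sham/Benzene replicate 1 (lowest, 9.91 CPM, next 17.7), Col6a6 in Sham/Benzene replicate 1 (lowest, 6.33 CPM, next 8.2), Csf3r in TAC/Air replicate 5 (highest, 4.07 CPM, next 3.43), Egln3 in TAC/Air replicate 5 (highest, 105 CPM, next 97.6) and Fgf10 in TAC/Benzene replicate 4 (highest, 0.588 CPM, next 0.262). A gap of that kind was also seen for Mt1 in TAC/Benzene replicate 4 (highest, 335 CPM, next 265), Cdh5 in Sham/Air replicate 3 (lowest, 242 CPM, next 265), Serpina3n in Sham/Benzene replicate 3 (highest, 55.8 CPM, next 37.8), Clu in Sham/Benzene replicate 3 (lowest, 730 CPM, next 846), Selp in TAC/Air replicate 3 (lowest, 0.856 CPM, next 1.4) and Thbs1 in TAC/Air replicate 4 (highest, 161 CPM, next 133). A gap of that kind was also seen for Sult1a1 in TAC/Air replicate 4 (lowest, 20.5 CPM, next 24.9), Sele in TAC/Benzene replicate 1 (lowest, 4.24 CPM, next 5.37), Kit in TAC/Benzene replicate 2 (lowest, 7.62 CPM, next 8.68), Dkk3 in TAC/Benzene replicate 5 (lowest, 44.2 CPM, next 47.3) and Hspb1 in TAC/Benzene replicate 6 (lowest, 311 CPM, next 376).

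The effect of benzene differed between TAC and sham mice, by the interaction term of edgeR, for 23 genes. Those with the higher effect after TAC, as log2 differences, were Pfkp at 0.467, Fkbp5 at 0.669, Myot at 0.689, Sele at 1.2, Lcn2 at 1.97, S100a8 at 1.98, S100a9 at 1.98, Retnlg at 3.14 and Mmp8 at 4.93. Those with the lower effect were Clec3a at -3.09, Chad at -2.64, Car3 at -1.95, Cyp2e1 at -1.95, Ecrg4 at -1.85, Wif1 at -1.3, Tgtp2 at -0.998, Scara3 at -0.914, Mgl2 at -0.815, H2-Q6 at -0.803, H2-Aa at -0.714, Cd74 at -0.688, H2-Ab1 at -0.679 and Irf9 at -0.588. Mmp8 (adjusted p = 0.00742), Cd74 (adjusted p = 0.0166) and Irf9 (adjusted p = 0.032) lie outside the rule for named genes in this comparison and were chosen after their values were seen. The median differences of the 8 lists called were 0.181 for the fetal program, -0.175 for matrix genes, 1.41 for neutrophil genes, -0.189 for macrophage and monocyte genes, -0.335 for interferon and antigen-presentation genes, -0.237 for complement and coagulation genes, 0.188 for glucocorticoid-responsive genes and -0.766 for atrial, mesothelial and nerve markers. Without Sham/Benzene replicate 4 the last was -0.47 and that of matrix genes -0.107, and without Sham/Air replicate 1 that of glucocorticoid-responsive genes was 0.0954.

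Neutrophil genes were higher in TAC/Benzene than in TAC/Air. With GC and length offsets the median log2 fold change was 1.935, against 1.90 without them, and the list stayed called (adjusted p = 4.597e-46), which argues against such a bias as the whole cause. The log2 ratio of summed globin transcripts was 0.1389 with a standard error of 0.4046. The bound set for that test assumed globin reads in numbers that track blood, but 10 globin genes held 61 counts in TAC/Air and 67 in TAC/Benzene, so blood left in the tissue stays open. More neutrophils in the tissue under benzene and TAC, a hypothesis from the same data, may also account for the pattern, and these data hold no cell counts.

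Sham/Air replicate 1 stood apart from the other libraries. Its median Spearman correlation with them was 0.937, and the lowest of the other Sham/Air libraries thinned to its total was 0.9715, which argues against low depth. Its median absolute log2 deviation fell from 0.8228 to 0.4654 with GC and length offsets, and the highest of the other 23 libraries was 0.153, so a GC or length trend may account for part of it and not for all. No biological explanation was tested, and the origin of the rest stays open.

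The lung transcripts Scgb1a1 and Sftpc were highest in Sham/Air. Lung RNA in the samples would bring the abundant lung transcripts together, and of 12 other lung markers 6 had their highest mean in Sham/Air (permutation p = 0.105 over 10000 permutations). Sftpa1 had 15 counts in Sham/Air, Scgb3a2 8, Sftpd 5 and Bpifa1 3, with 0 in each other group. Sftpb had 12 in Sham/Air against 23 in TAC/Benzene, and Napsa 29 against 84 in TAC/Air. The markers found only in Sham/Air go with lung RNA there. It still cannot be told apart from other origins, since most of these markers had few counts. TAC/Air, which breathed no benzene, had 0.135 ± 0.135 CPM of Scgb1a1 and 0.0563 ± 0.0721 CPM of Sftpc, against 6.32 ± 1.53 and 1.85 ± 0.664 in Sham/Air (SD, n = 6). The log2 fold change of the gene nearer to 0, Sftpc, was -4.9 with a standard error of 0.6137, which argues against lower expression under benzene as the whole cause. Whether benzene has a part in the difference within sham mice stays open.

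Each comparison was also made on 100 splits of its libraries into groups of the same sizes, the real one included. For TAC in air 1 split, the real one, gave as many as 2193 genes and the highest other gave 1089. The real split was also the only one as large for TAC in benzene (2257 genes, highest other 663) and benzene in TAC (79 genes, highest other 0). The same held for the interaction (23 genes, highest other 0). A second draw of 100 splits gave 1 split as large for each of these comparisons, with highest others of 1082, 531, 0 and 21. With 100 splits in a draw the test bounds the share of splits as large, and it cannot exclude chance. For benzene in sham, with 3 genes, 1 split was as large in the first draw (highest other 2) and 4 in the second (highest other 2764). The share was under 0.05 in both, but 2 of the 3 calls ended when a single library was left out, that of Hspa1b for each of 6 libraries and that of Sftpc for each of 11. For the averaged effect, with 26 genes, 2 splits were as large in the first draw (highest other 1873) and 1 in the second (highest other 12), shares under 0.05. The split with 2764 genes had a gap of 0.631 between its groups in mean GC rank correlation, against 0.0488 for the real groups, and no split of its draw had a wider one. The averaged split with 1873 genes had a gap of 0.466 against 0.099, and 1 split had a wider one. The split with 1082 genes had a gap of 0.297, and 25 splits of its draw had a wider one. That split put Sham/Air replicates 2 to 6 with TAC/Air replicate 3. The split with 663 genes put TAC/Benzene replicates 1 to 5 with Sham/Benzene replicate 4. The one with 531 genes put TAC/Benzene replicate 4 with Sham/Benzene replicates 1, 2, 3, 5 and 6. The split with 12 averaged and 21 interaction genes kept all TAC/Air libraries together. These groups lie near the real ones, so their counts can hold part of the real effect. The splits with 2764 and 1873 genes call many times the real count and point to a structure of the libraries.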

How the results depend on the processing

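The GC and length offsets were chosen after the data were seen, and the other alternatives before the data were examined. In the order TAC in air, TAC in benzene, benzene in sham, benzene in TAC, averaged and interaction, 2193, 2257, 3, 79, 26 and 23 genes were called. None of the 161 calls of named genes reversed its sign, and no list called the direction of its test, under any alternative run. The other called genes were not checked for sign. The median of a called list changed sign in 5 cases. It did so without the low-count filter for atrial, mesothelial and nerve markers after TAC in air (-0.34 to 0.12) and cytokine genes for benzene in TAC (0.11 to -0.0071), and in the latter comparison for cytokine genes without TAC/Air replicate 5 (-0.035) and antioxidant genes (0.016) without TAC/Air replicates 4 or 6 (-0.0040 and -0.0051). Counts that moved by over 1.5 times were, with limma-voom, 3739, 4497, 6, 556, 187 and 93, with GC and length offsets 3595, 3644, 18, 241, 145 and 55, and with those offsets on 23 libraries 4266, 4862, 38, 619, 328 and 184. DESeq2 gave 28, 171, 103 and 57 for the last 4 comparisons, a fit of only the 2 groups compared 1278 for TAC in air, 1 for benzene in sham and 276 for benzene in TAC, and no low-count filter 1 for benzene in sham. The cause was not tested. Higher and lower calls, 1 and 2 in sham, became 16 and 12 with DESeq2, 10 and 8 with offsets, 22 and 16 with offsets on 23 libraries, 0 and 1 without the filter or with only 2 groups, and 1 and 1 with a mean of at least 1 CPM. Averaged over surgery, 17 and 9 became 55 and 48 with DESeq2, 94 and 93 with limma-voom, 70 and 75 with offsets and 173 and 155 with offsets on 23 libraries. For the interaction, 9 and 14 became 28 and 29 with DESeq2 and 51 and 42 with limma-voom. Relative log expression size factors moved no count by over 1.5 times. Leaving out 1 library gave 1907 to 3169, 1929 to 2233, 1 to 5, 52 to 68, 16 to 101 and 15 to 49 genes. In sham the count was 1 without Sham/Air replicates 2, 3, 4, 5 or 6 and 5 without Sham/Benzene replicate 1. It was 52 for benzene in TAC without TAC/Benzene replicate 2. Averaged, it was 101 without Sham/Air replicate 1, 17 without TAC/Air replicate 5 and 16 without TAC/Benzene replicate 4, and for the interaction 49 without Sham/Air replicate 1 and 15 without Sham/Air replicate 4. With the replicate number as a block the counts were 1867, 1951, 2, 46, 15 and 14, with 0 higher and 2 lower in sham and 7 and 7 for the interaction. The numbers were not taken to pair the libraries, since in no set of groups did all same-numbered pairs correlate over 0.1. Of 6 pairs, 0, 1, 4 and 5 did between Sham/Air and TAC/Air, Sham/Benzene and TAC/Benzene, Sham/Air and Sham/Benzene, and TAC/Air and TAC/Benzene. Within these, 0 and 0, 0 and 1, 1 and 2, and 2 and 3 of 6 libraries of the first and second group correlated best with their own number, and the highest correlations of same-numbered libraries were 0.635 in sham and 0.596 in TAC. GC rank correlations were below 0 in replicates 1 to 3 and above 0 in 4 to 6 of both sham groups, and the other way in TAC/Air. No term for replicates 1 to 3 against 4 to 6 was fitted, so a structure shared between groups stays open. Of 161 calls of named genes, DESeq2 lost 0, limma-voom 3, GC and length offsets 6, no filter 10 and the block 26 (1, 8, 10 and 7 in the last 4 comparisons), and of 118 the fit of only 2 groups lost 4. The block ended the call of Hspa1b in sham (adjusted p = 0.304). For benzene in TAC it ended those of Snrpn, Efemp1, Ecrg4, Tnc, Bnip3, Mt2, Mt1 and Rrm2. Averaged, it ended those of Hspa1b, Hspa1a, Agt, Mt2, Smoc1, Col6a6, Gatm, Fhl1, Cdkn1a and Manf. For the interaction it ended those of Sele, Pfkp, Wif1, Scara3, Mgl2, H2-Q6 and H2-Ab1. Smoc1 and Gatm averaged and H2-Ab1 for the interaction kept their calls whichever library was left out, yet lost them with the block. Of 69 list calls, an estimated correlation lost 27, GC and length offsets 4, those on 23 libraries 3, no filter 1 and the block 0. Gained were 5 list calls with GC and length offsets, 11 with those on 23 libraries, 7 with no filter and 9 without Sham/Air replicate 1. Only-2-groups fits give no averaged or interaction value, and DESeq2 and limma-voom were not used for lists. In simulated counts for benzene in TAC, 39 of 67 genes changed 1.5-fold were recovered, so changes of that size or smaller can be missed. The simulated counts held no GC trend and no library apart, so recovery in the real libraries can be lower.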

Other observations

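The measure of spread within groups, its matched lists and the lists named for it were chosen after the data were seen, and the 28 gene lists before. The lists of some cell types and processes were not called in any of the 6 comparisons with all libraries and the filter on low counts, though some were called under alternatives. Ribosomal protein genes had 1 of 37 higher after TAC in air and 1 lower after TAC in benzene (adjusted p = 0.603 and 0.706), and 0 for benzene in TAC (adjusted p = 0.511). Circadian clock genes had 4 of 20 higher and 3 lower after TAC in air (adjusted p = 0.603), and 4 higher and 6 lower in benzene (adjusted p = 0.32). Smooth muscle and pericyte markers had 3 of 16 higher and 2 lower after TAC in air, and 1 higher and 2 lower in benzene (adjusted p = 0.603 and 0.717). Adipocyte markers had 1 of 11 higher after TAC in air (adjusted p = 0.801), 2 lower after TAC in benzene (adjusted p = 0.313), 1 lower for benzene in TAC (adjusted p = 0.126) and 1 lower for the interaction (adjusted p = 0.101). Erythroid and blood genes had 0 of 9 called in each comparison by edgeR, at adjusted p from 0.436 to 0.982 for the list. Without the low-count filter the adipocyte list was called for benzene in TAC (adjusted p = 0.025) and the interaction (adjusted p = 0.0287). With GC and length offsets on 23 libraries the circadian list was called for TAC in benzene (adjusted p = 0.0378) and the smooth muscle and pericyte list for the interaction (adjusted p = 0.0273). The latter was also called for the interaction without Sham/Air replicate 5, Sham/Benzene replicate 2, TAC/Air replicate 4 or TAC/Air replicate 6 (adjusted p = 0.0492, 0.043, 0.0228 and 0.049). The adipocyte list was called for the interaction without Sham/Benzene replicate 1 or 3 (adjusted p = 0.0411 and 0.0155), and the ribosomal list for the averaged effect without Sham/Air replicate 1 (adjusted p = 0.0382).

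The variance within groups over counting noise was set against 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean count. In Sham/Benzene 14 of 28 lists lay above the 95th percentile of their matched lists, in Sham/Air without replicate 1 3, in TAC/Air 5 and in TAC/Benzene 6, where chance gives about 1 in 20. Without Sham/Benzene replicate 4 it was 11, and 8 at a permutation p adjusted over the 28 lists, against 14 with it. Respiratory chain and ribosomal protein genes lay above that percentile in all 4 groups, at 99.4 and 36.3 in Sham/Benzene, where their matched lists had medians of 39.9 and 17.3. Among the others, chaperone and heat shock genes had 21.7 in Sham/Benzene (matched 6.86), immediate early genes 19.1 (matched 3.90), glucocorticoid-responsive genes 12.1 (matched 5.30), adipocyte markers 12.03 (matched 4.11) and circadian genes 10.8 (matched 4.72). Without replicate 4, the highest of its group in several chaperone and immediate early genes, these had 19.1, 8.93, 11.6, 10.7 and 9.88, still above the 95th percentile of their matched lists. In Sham/Air without replicate 1 the same 5 lists had 3.45, 2.15, 3.28, 1.99 and 2.03, in TAC/Air 5.33, 4.42, 5.28, 2.82 and 2.62, and in TAC/Benzene 3.18, 3.04, 2.80, 3.95 and 2.84, all below that percentile except the adipocyte markers in TAC/Benzene. Members of a list can vary together, which random lists do not, so these percentiles describe the libraries only.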
